A study of Canis lupus familiaris with 8 samples.

How the data were processed

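Total RNA from cardiac tissue of 8 male dogs, 4 controls and 4 given methionine in their water for 2 weeks, was hybridised to Affymetrix canine arrays, 1 array per dog, per the labels. The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. The deposited arrays share a mean signal of about 500.1 units once 2% is left out at each end, so no further scaling was done. Detection calls and scanner files were not used here. Samples were grouped by their titles. The replicate numbers run from 1 to 4 in controls and from 5 to 8 in HHcy, and no batch or date is given in the labels. The labels speak of separate dogs, so the spread between arrays covers animals and handling together.

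The platform annotation gave 1 symbol for 10549 probe sets, several for 138 and none for 13226, control probe sets included. Of those with 1 symbol, 10046 matched the RefSeq gene table by gene identifier, and 0 symbols needed updating. Gene names were not checked against probe sequences. No coordinates were used, since no build is named for the array.

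Values were analysed as log2(value + 24), 24 being the 20th percentile of all values, so folds of dim genes are understated. The 77 control probe sets were left out, then the dimmest 40% by mean log2 value over all arrays, which left 14301. Groups were compared with limma (version 3.58.1, R version 4.3.3), using lmFit and eBayes with an intensity trend and Benjamini-Hochberg adjustment at 0.05. Errors of log2 fold changes are standard errors, and those of signals are standard deviations. Gene lists were tested with camera, preset correlation 0.01, on the brightest probe set of each gene, for lists with at least 5 measured members.

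The rule for named genes and the 44 lists were written before the data were examined. The rule took the 12 genes highest and the 12 lowest by fold among those passing, or by unadjusted p where fewer than 12 passed. It also took from each list up to 4 passing members or else the 2 of lowest p, and 24 genes chosen for the study's themes where measured. It named 109 genes, of which those that matter most are described. For genes with several probe sets, the brightest is given and disagreements are stated.

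The procedure was tested on simulated data for this comparison, with 14301 probe sets, 200 of them changed. It recovered 12% of 50 probe sets changed by 1 log2 unit, 72% at 2, 84% at 3 and 88% at 4, with 7 false calls among 135. A simulation with no change gave 0 calls. Simulated lists gave 0 calls among 38 with no change. Every gene was drawn independently in the simulations, so they do not show how the list test behaves when genes vary together.

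Alternatives tried were quantile, median and trimmed-mean scaling, pseudocounts of 6 and 96, no filter and a filter on the dimmest 60%, other variance models, array weights, a minimum fold of 1.2, 1 probe set per gene, leaving out each array, and for lists other tests and summaries. Alternatives chosen after seeing the data left out HHcy 5 and HHcy 6, left out control 2 and HHcy 6, or used the mean log2 3'/5' ratio of actin and GAPDH as a covariate. All 35 splits of the 8 arrays into 4 and 4 were run.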

Results

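Cardiac gene expression was measured on Affymetrix canine arrays in 8 male dogs of 23 to 27 kg, 1 array per dog. Hyperhomocysteinemia (HHcy), a raised blood level of the amino acid homocysteine, was induced in 4 dogs by methionine in the drinking water for 2 weeks, and 4 dogs served as controls. The labels give the tissue as cardiac and do not name the chamber. The question set by the series is how chronic HHcy changes gene expression in the heart, with substrate metabolism, nitric oxide and oxidative stress in its title. Each array held 23913 probe sets, and its trimmed mean signal lay between 500.08 and 500.10 units. Of these probe sets, 14301 were bright enough to be tested, and 7288 of them carried 1 gene symbol, for 5015 genes. The number of arrays, 4 per group, limits the precision of every value below.

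SAA1, C3, CXCL8, C6 and REG3A were among the transcripts that were higher in the hearts of HHcy dogs. SAA1, an acute-phase serum amyloid A protein, rose 25.1-fold (log2 fold change 4.65 ± 0.44, SE), from a signal of 161 ± 69.3 (SD, n = 4) in controls to 4998 ± 2575 (SD, n = 4). The complement component C3 rose 13.3-fold (log2 fold change 3.73 ± 0.39, SE), from 494 ± 161 to 7156 ± 2906 (SD, n = 4 each). CXCL8, the neutrophil-attracting chemokine interleukin 8, rose 9.91-fold, with folds of 5.62 and 12.7 at pseudocounts of 96 and 6. C6, a component of the membrane attack complex, rose 5.53-fold. REG3A, a secreted antimicrobial lectin, rose 39.9-fold on its brightest probe set, from 20.7 ± 7.33 to 2934 ± 2881 (SD, n = 4 each), and also rose on a second one, from 8.98 ± 3.69 to 3235 ± 2748 (SD, n = 4 each). These control signals lie under the pseudocount of 24, so the folds depend on it. On the brightest REG3A probe set the fold was 66.7 with a pseudocount of 6, and 16.4 with one of 96, where it did not pass (limma adjusted p 0.0574, range over its alternatives 0.000162 to 0.229).

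In all, 14 of the 14301 probe sets changed with limma and Benjamini-Hochberg adjustment, 14 higher and 0 lower in HHcy (849 lower at an unadjusted p under 0.05). The adjusted p was 0.00371 for SAA1, 0.00377 for C3, 0.0120 for CXCL8, 0.0267 for the brightest REG3A probe set and 0.0289 for C6. SMPDL3A, a phosphodiesterase related to acid sphingomyelinase, rose 7.10-fold (adjusted p 0.0149). LOC751814 rose 11.8-fold (adjusted p 0.00377), and a pair of LOC403585 probe sets rose from 10.3 ± 1.40 to 287 ± 128 and from 8.84 ± 3.18 to 814 ± 825 (SD, n = 4 each), with a limma adjusted p of 0.0289 for each. No fold is given for the pair, whose control signals lie under the pseudocount, and with a pseudocount of 96 the adjusted p was 0.0433 and 0.0832 (range over the alternatives of LOC403585 0.00181 to 0.768). LOC751814 and LOC403585 both carry the synonym SAA in the RefSeq gene table, so they can share sequence with SAA1 and are not independent of it. LOC403585 was named after its values were seen. Its brightest probe set had a log2 fold change of 0.30 (adjusted p 0.765), and its remaining probe sets ran from 1.70 down to -0.39, none of them passing. The other 4 changed probe sets have no symbol and rose 6.52-fold to 9.63-fold, 1 of them from a control signal under the pseudocount. For each of the 14, every HHcy array lay above every control array.

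**Figure D1:**
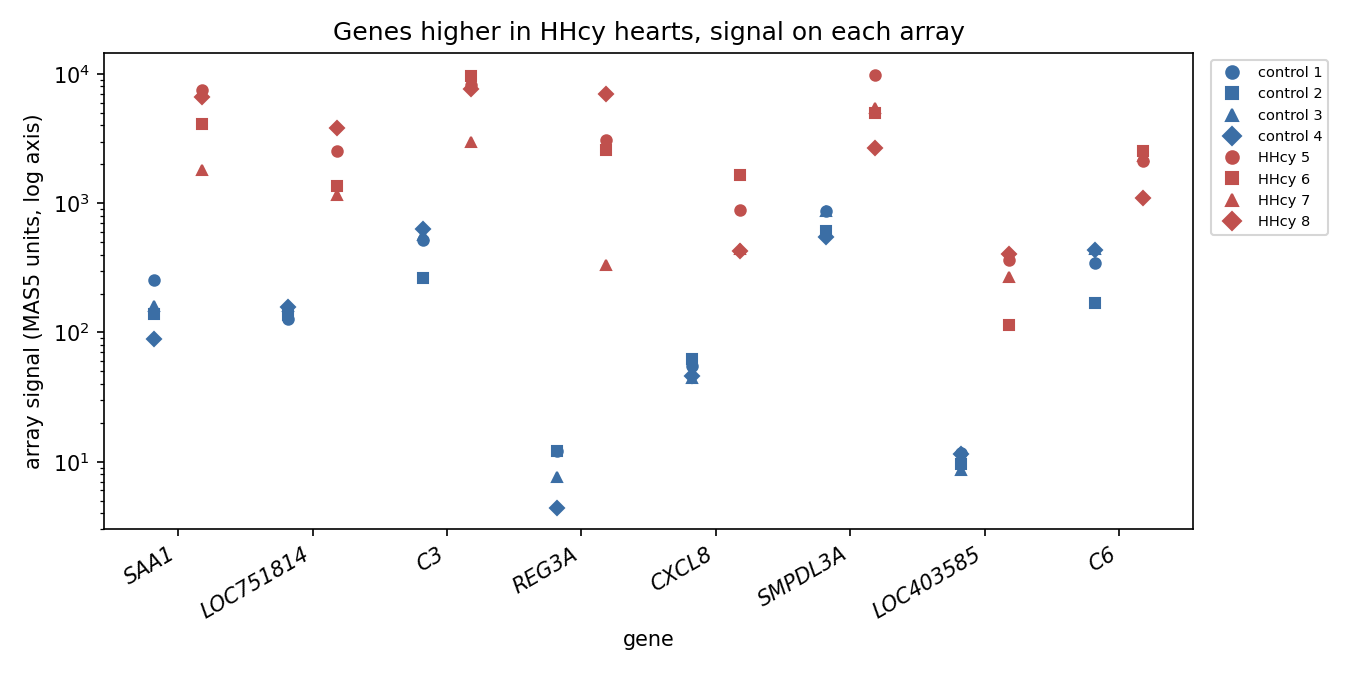
Signal on each array, in MAS5 units on a log axis, of the 8 gene symbols with a changed probe set, each drawn for its probe set of lowest p. Points are single arrays, blue for control and red for HHcy. The 4 HHcy arrays lie above the 4 control arrays for each gene, with SAA1 between 88.6 and 254.4 in controls and between 1798.3 and 7473.3 in HHcy.

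Other probe sets of the same genes did not always pass. Other C3 probe sets had log2 fold changes of 2.21 (adjusted p 0.0866) and 0.91 (adjusted p 0.306), and a further LOC751814 probe set had 1.92 (adjusted p 0.158). Another REG3A probe set had 3.67 (adjusted p 0.0845). Without HHcy 7 that REG3A probe set and the C3 probe set at 2.21 passed, with 4.22 and 2.57. At an unadjusted p under 0.05, limma found 2549 probe sets, 1700 higher and 849 lower, where 715 would be expected by chance. Other splits of the 8 arrays into 4 and 4 gave from 147 to 1490 such probe sets, so the number varies widely around that expectation. All of them lay under the 2549 of the real split, and the split with 1490 kept HHcy 5, HHcy 6 and HHcy 8 together. The 2 groups did not overlap in 11.4% of the probe sets, against 2.86% by chance. The median log2 fold change over all probe sets was 0.15, and quantile scaling brought it to 0.011 and median scaling to -0.19, so small fold changes below are to be read against that shift. The split at an unadjusted p under 0.05 was 1148 higher and 1156 lower with quantile scaling, and 674 higher and 1930 lower with median scaling.

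The count of 14 depended on which arrays were included. It was 9, 3, 4 and 3 without control 1, 2, 3 and 4 in turn, 5 without HHcy 5, and 31 without HHcy 8, of which 22 were higher and 9 lower. SAA1, C3 and LOC751814 passed in each of the 8 settings that leave out 1 array. CXCL8 had an adjusted p of 0.0712, 0.0576, 0.0572 and 0.0771 without control 2, 3 and 4 and HHcy 5, and SMPDL3A 0.1001, 0.0576 and 0.0780 without control 2, 3 and 4. The brightest REG3A probe set had 0.0766, 0.122, 0.0667 and 0.0868 without control 1, 2, 3 and 4 and 0.121 without HHcy 5, and its fold was 72.8 without HHcy 7 and 25.3 without HHcy 8. C6 had 0.0766, 0.0961, 0.0667 and 0.0821 without control 1, 2, 3 and 4, and 0.133 and 0.0881 without HHcy 5 and HHcy 7. The LOC403585 probe set with a signal of 287 in HHcy passed only without HHcy 6, its adjusted p in the other 7 settings running from 0.0664 without HHcy 8 to 0.164 without HHcy 5. Without both HHcy 5 and HHcy 6, 5 probe sets passed, all higher, and 4 of them belonged to the 14: C3, LOC751814, SAA1 and 1 of LOC403585. The other was the apolipoprotein APOC1, named after its values were seen. In that setting SAA1 was 19.9-fold and C3 9.72-fold higher, CXCL8 had a fold of 6.03 (adjusted p 0.0712, range over its alternatives 0.00103 to 0.0779) and C6 a fold of 4.60 (adjusted p 0.248, range 0.0132 to 0.362).

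Among genes just short of the threshold, the protease inhibitor SERPINA1 had a signal of 18.4 ± 13.0 in controls and 526 ± 438 in HHcy (SD, n = 4 each, limma adjusted p 0.0603), and no fold is given since the control signal lies under the pseudocount, so that the log2 fold change was 2.18 with a pseudocount of 96 and 4.21 with one of 6. Also just short were uridine phosphorylase UPP1, with a fold of 3.19 (adjusted p 0.0612), and the metalloproteinase inhibitor TIMP1, with a fold of 3.88 (adjusted p 0.0613). SRGN, a proteoglycan of secretory granules, and DMXL2 had folds of 4.41 and 2.66, with an adjusted p of 0.0866 for each. Without HHcy 8 the adjusted p was 0.0165 for SERPINA1, 0.0312 for TIMP1, and 0.0394 for SRGN, the collagen COL1A2 and, in the lower direction, FAU, and without HHcy 6 it was 0.0464 for SRGN. With array weights SERPINA1, UPP1, TIMP1, SRGN and DMXL2 passed, with an adjusted p from 0.0173 for UPP1 to 0.0404 for DMXL2 (highest over the alternatives 0.501, 0.506, 0.591, 0.538 and 0.839), and SERPINA1 also passed with median scaling (adjusted p 0.0384). In the lower direction no named gene passed in the comparison itself. PPP5C had an adjusted p of 0.0476 with median scaling, 0.0337 without an intensity trend and 0.0404 with array weights, and BIRC6 0.0404 with array weights (ranges over their alternatives 0.0337 to 0.633 and 0.0404 to 0.538). The 12 with the lowest unadjusted p there were PPP5C, BIRC6, GNG14, CALU, MAP3K15, PSMC5, CCDC91, AP1S2, TRAPPC8, EIF4A2, FAU and CCSER2. Their adjusted p ran from 0.0863 for PPP5C, a protein phosphatase with a log2 fold change of -2.13 ± 0.40 (SE), to 0.144 for CCSER2. The HHcy signal of PPP5C, 22.8 ± 13.4 (SD, n = 4), lies under the pseudocount, and with one of 96 its log2 fold change was -1.20. Other probe sets of CALU, FAU and CCSER2 had 0.14, 1.0 and 0.10.

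RNA quality signs differed between arrays. The 3'/5' signal ratio of actin was 15.3 on HHcy 5 and 599.6 on HHcy 6, against 0.378 to 2.49 on the controls. That of GAPDH was 17.2 and 10.5 on the same arrays, against 1.46 to 3.76 on the controls. The mean log2 3'/5' ratio was 3.38 ± 2.28 in HHcy and 0.90 ± 0.90 in controls (SD, n = 4 each), which did not pass an exact two-sided permutation test (p = 0.0857, the smallest possible being 0.0286). HHcy 6 had the lowest mean correlation with the other arrays, 0.784, and the lowest array weight, 0.278.

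**Figure D2:**
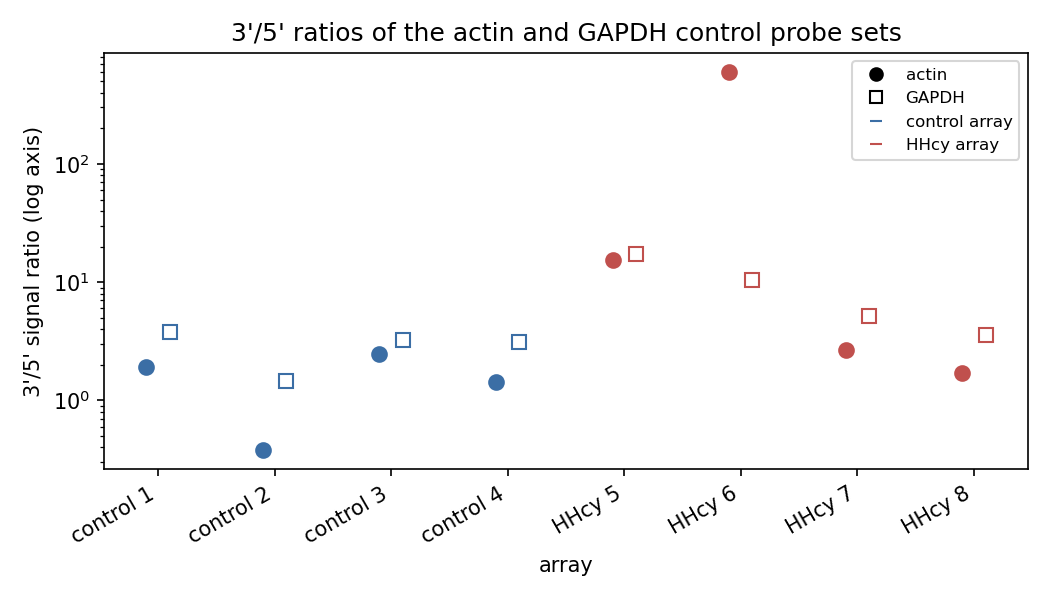
Ratio of 3' to 5' signal, on a log axis, for the actin control probe sets (filled circles) and the GAPDH control probe sets (open squares) on each array, blue for control and red for HHcy. The actin ratio is 599.6 on HHcy 6 and 15.3 on HHcy 5, and at most 2.67 on the other arrays.

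Gene lists fixed before the data were examined gave a further view. Of 44 lists, 38 had at least 5 measured members and 15 passed limma's camera test with a preset correlation of 0.01, 4 higher and 11 lower in HHcy. With an estimated correlation camera called 0 (3 at an unadjusted p under 0.05), and the smallest adjusted p was 0.512. With limma's fry test 2 passed, the macrophage markers (adjusted p 0.0270) and the inflammation list (adjusted p 0.0342). These 2 lists share members, CD14 among them, and the muscle lists share others such as MYL3, so list results are not independent. Other splits of the same 8 arrays into 4 and 4 gave up to 16 lists.

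The inflammation and adhesion list, with 20 measured members, had a median log2 fold change of 0.85 (camera adjusted p 1.49e-05; adjusted p = 0.512 with an estimated correlation). SAA1, C3 and CXCL8 passed over all probe sets, and 9 of the 20 were higher adjusted over the list alone. The macrophage markers had a median of 1.26, higher on all 4 HHcy arrays (camera adjusted p 1.49e-05; adjusted p = 0.512 with an estimated correlation). None of the 12 measured markers passed over all probe sets, and 9 were higher adjusted over the list alone. FCGR1A, an antibody receptor, had a fold of 2.87, and CD14, a lipopolysaccharide co-receptor, a fold of 2.67, each with an adjusted p of 0.121. Without HHcy 5 and HHcy 6, the camera adjusted p was 0.000189 for the macrophage markers (range over their alternatives 3.79e-07 to 0.512) and 0.000341 for the inflammation list (range 1.29e-07 to 0.512).

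Interferon and antigen presentation genes had a median of 0.59 over 16 members (camera adjusted p 0.00382; adjusted p = 0.546 with an estimated correlation), and 4 were higher adjusted over the list alone. TAP1, a peptide transporter, had a fold of 2.27 and the protease CTSS a fold of 2.43, neither passing over all probe sets. Extracellular matrix genes had a median of 0.62 over 37 members (camera adjusted p 0.00303; adjusted p = 0.565 with an estimated correlation), and 3 were higher adjusted over the list alone. Fibronectin FN1 had a log2 fold change of 2.17 ± 0.45 (SE, adjusted p 0.113; 0.0376 with array weights, range 0.0376 to 0.863), although another FN1 probe set had a log2 fold change of -0.17. The matrix call was lost without HHcy 6, where the camera adjusted p was 0.0617 (range over its alternatives 2.16e-05 to 0.899). That array had the highest matrix median, 1.35, and the highest fibroblast marker median, 1.37.

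Contractile and mitochondrial lists had lower medians, and these rested largely on HHcy 6. Sarcomere genes had a median log2 fold change of -1.23 over 23 members (camera adjusted p 5.62e-07; adjusted p = 0.546 with an estimated correlation), and oxidative phosphorylation genes -0.42 over 48 members (camera adjusted p 5.62e-07; adjusted p = 0.565 with an estimated correlation). On HHcy 6 the sarcomere median was -4.07 and that of oxidative phosphorylation -2.15, against -0.21 to 0.0020 and -0.029 to 0.18 on the other HHcy arrays, within the -0.21 to 0.28 and -0.17 to 0.23 of the controls. The ventricular light chain MYL3 had a signal of 27.4 on HHcy 6 and of at least 6933.3 on every other array. Cardiomyocyte markers had a median of -4.77 on that array. No member of these lists, each taken by its brightest probe set, passed over all probe sets or adjusted over the list alone. Without HHcy 8, other probe sets of the myosin heavy chain MYH7, the complex I subunit NDUFB8 and the ATP synthase subunit ATP5MC2 passed as lower, with log2 fold changes of -2.57, -2.98 and -2.97. With all arrays they had -2.10, -2.28 and -2.45 and did not pass, and the brightest probe sets of the same genes had -0.44, -0.041 and -1.10. These genes were named after their values were seen.

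Without HHcy 6, 6 lists passed, 3 higher and 3 lower. Inflammation, macrophage and interferon genes stayed higher, while sarcomere (adjusted p 0.00623), calcium handling (adjusted p 0.00623) and atrial myocyte genes (adjusted p 0.00885) stayed lower. With all arrays and an estimated correlation the adjusted p = 0.546 for sarcomere and calcium handling genes and 0.512 for atrial genes. The calcium handling medians on HHcy 5, 7 and 8 were -0.29 to -0.13, against -0.16 to 0.21 on the controls, and the atrial medians -1.0 to -0.45, against -0.41 to 0.31. The adjusted p was then 0.415 for oxidative phosphorylation, 0.191 for pyruvate oxidation and the TCA cycle, 0.0583 for fatty acid oxidation, 0.897 for heat shock proteins, 0.134 for stress and fetal heart genes, 0.208 for the proteasome, 0.227 for cardiomyocyte markers and 0.0732 for ventricular markers. With all arrays and an estimated correlation the adjusted p = 0.620 for heat shock proteins, 0.512 for stress and fetal heart genes and 0.546 for the proteasome, cardiomyocyte and ventricular lists. Over all alternatives these 8 ranged up to 0.571, 0.899, 0.546, 0.988, 0.899, 0.899, 0.546 and 0.953, and sarcomere, calcium handling and atrial genes up to 0.699, 0.730 and 0.512. Heat shock proteins were also lost without control 1 (0.0585) and control 4 (0.0764), stress and fetal heart genes without control 1 (0.0585) and control 2 (0.0742), and ventricular markers without control 2 (0.0627). Without both HHcy 5 and HHcy 6 the adjusted p was 0.0963 for atrial genes and 0.0375 for ventricular markers. With the 3'/5' ratio as a covariate, sarcomere genes (0.699) and ventricular markers (0.953) turned to the higher direction. Of the 5 measured atrial markers, 3 were lower adjusted over the list alone: the light chain MYL7, the potassium channel KCNA5 and the peptide-processing enzyme PAM. A further KCNA5 probe set had a log2 fold change of 0.40.

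**Figure D3:**
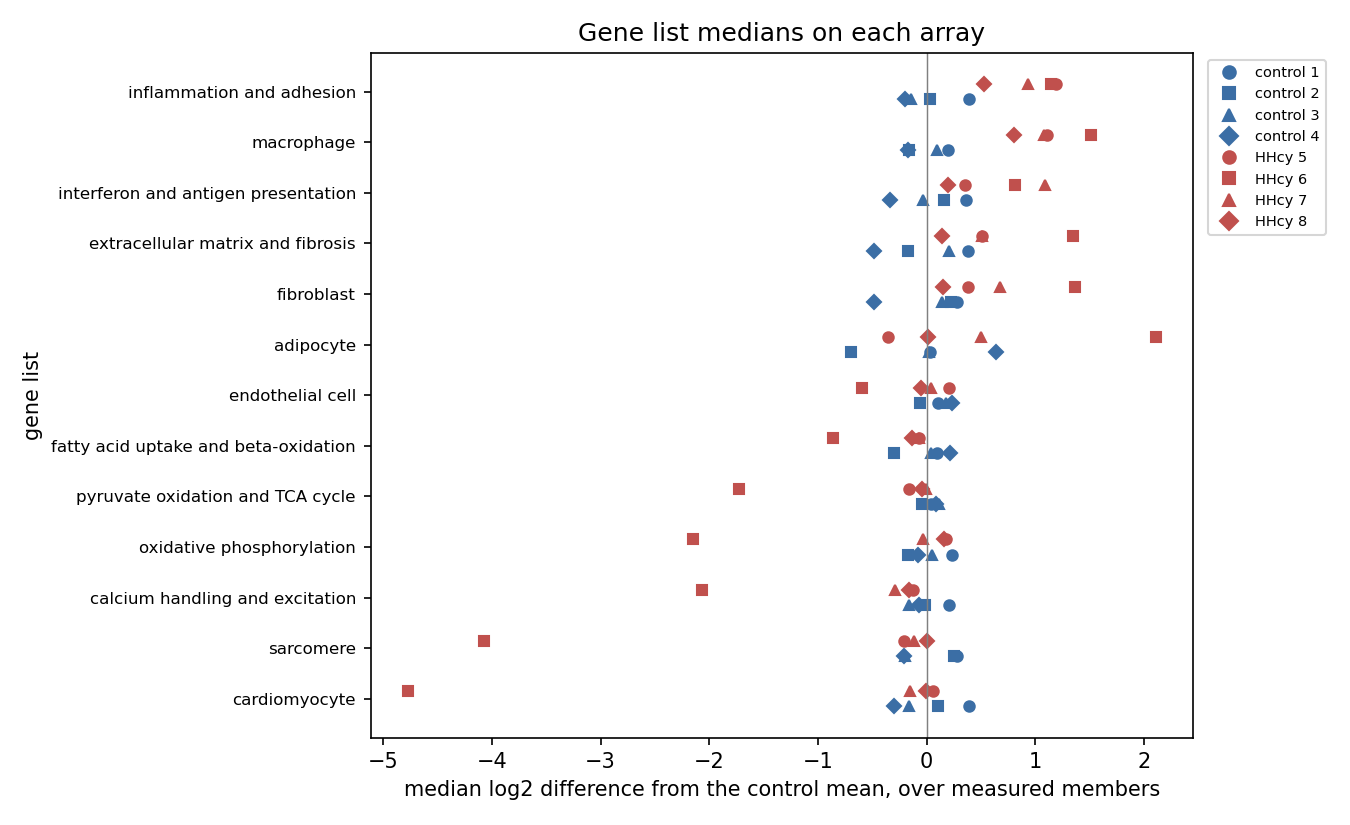
Median log2 difference from the control mean over the measured members of gene lists, for each array, blue for control and red for HHcy. HHcy 6 lies far below the other arrays for cardiomyocyte (-4.77), sarcomere (-4.07) and oxidative phosphorylation genes (-2.15), while macrophage medians are above 0 on the 4 HHcy arrays (0.81 to 1.51).

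For substrate metabolism, nitric oxide and oxidative stress, no single gene passed. Fatty acid uptake and oxidation genes had a median log2 fold change of -0.29 over 23 members (camera adjusted p 0.00284; adjusted p = 0.546 with an estimated correlation), and pyruvate oxidation and TCA cycle genes -0.37 over 23 members (camera adjusted p 0.000274; adjusted p = 0.546 with an estimated correlation). Both medians were lowest on HHcy 6, at -0.86 and -1.72, against -0.14 to -0.071 and -0.16 to -0.0070 on the other HHcy arrays and -0.30 to 0.22 and -0.040 to 0.12 on the controls. Without HHcy 6 neither list passed (adjusted p 0.0583 and 0.191, ranges over their alternatives 0.000407 to 0.546 and 2.95e-05 to 0.899), although the fatty acid list passed without control 2 and HHcy 6, and with the 3'/5' ratio as a covariate the TCA cycle list turned to the higher direction (0.899). HADH, an enzyme of beta-oxidation, had a log2 fold change of -1.22 ± 0.38 (SE, adjusted p 0.171), and the glucose transporter SLC2A1 had -0.87 ± 0.29 (SE, adjusted p 0.192). Glucose uptake and glycolysis genes did not pass as a list (camera adjusted p 0.108), nor did nitric oxide and cGMP genes (0.222), antioxidant genes (0.709, with a median of 0.0072 although camera's direction was lower), methionine and one-carbon genes (0.574) or superoxide sources and the angiotensin system (0.0980). That last list had a median of 0.78 over 12 members, and passed as higher with median scaling (adjusted p 0.0290), with the dimmest 60% left out (0.0459) and without HHcy 7 (0.0146), within a range of 0.0146 to 0.915 over its alternatives. Its median was 1.06 on HHcy 5 and 1.18 on HHcy 6, against -0.061 on HHcy 7, 0.32 on HHcy 8 and -0.17 to 0.16 on the controls. Without HHcy 5 and HHcy 6 the camera adjusted p of that list was 0.828. Its camera adjusted p with all arrays and an estimated correlation was 0.546. Glycolysis genes passed as lower with no filter on dim probe sets (adjusted p 0.0243, range 0.0243 to 0.979). With the filter and an estimated correlation their camera adjusted p was 0.546.

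Of 24 genes chosen beforehand for these themes, 15 were measured brightly enough to test and limma called 0 of them (2 at an unadjusted p under 0.05). NOS3, the endothelial nitric oxide synthase, had a log2 fold change of 0.32 ± 0.35 (SE, adjusted p 0.642), which turned to -0.047 with median scaling. That NOS3 probe set had a control signal of 14977 ± 7134 (SD, n = 4) and is named by the platform annotation alone, and another NOS3 probe set had -0.14 (adjusted p 0.850). The NADPH oxidase subunit CYBB had 0.66 ± 0.38, superoxide dismutase SOD1 0.49 ± 0.33, SOD2 -0.60 ± 0.35 and catalase CAT 0.51 ± 0.25 (SE, n = 4 each). Another SOD2 probe set had 0.28, and other CAT probe sets had 0.54, -0.42 and -0.51. PDK4, which restrains pyruvate oxidation, had 0.30 ± 0.41 (-0.061 with median scaling), ACADM, a fatty acid dehydrogenase, -0.19 ± 0.27 (0.037 without HHcy 6 and 0.075 with array weights), and PDHA1, a pyruvate dehydrogenase subunit, -0.75 ± 0.33 (0.72 and -0.50 on other probe sets). The methionine cycle enzymes AHCY and MAT2A had 0.046 ± 0.24 (-0.065 with quantile and -0.30 with median scaling, -0.046 without HHcy 6 and -0.042 with array weights) and -0.31 ± 0.20. Other MAT2A probe sets had larger changes in the same direction, -1.31 (limma adjusted p 0.121) and -0.89 (limma adjusted p 0.171). The calcium pump ATP2A2 had -0.70 ± 0.53, with a signal of 4061.3 on HHcy 6, and -0.032 without that array. Other ATP2A2 probe sets had -2.09, -1.74, -0.053, 0.0062, 0.029, 0.043 and 0.17. The glycolytic enzyme GAPDH had -2.04 ± 1.02, with a signal of 156 on HHcy 6 against at least 3733.7 on every other array, and -0.72 without HHcy 6 and -2.73 without HHcy 8. The uncoupling protein UCP3 had -0.22 ± 0.58, which turned to 0.38 without HHcy 6, 0.045 without control 4 and 0.090 with array weights. The thioredoxin inhibitor TXNIP had 0.46 ± 0.29, and another TXNIP probe set -2.53. Without control 2 and HHcy 6 the direction also turned for SOD1 (-0.022), ACADM (0.12), AHCY (-0.083), UCP3 (0.26) and ATP2A2 (0.053), and without HHcy 5 and HHcy 6 for NOS3 (-0.059), ACADM (0.011) and AHCY (-0.13). With the 3'/5' ratio as a covariate it turned for NOS3 (-0.042), SOD1 (-0.074), SOD2 (0.13), ACADM (0.21), AHCY (-0.19), UCP3 (0.42), GAPDH (0.58) and ATP2A2 (0.34).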

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

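The tests of RNA quality, scaling, macrophage share, fat or fibrous tissue and myocyte share were chosen after the results were seen; those of mesothelial tissue, regrouping and general RNA loss were fixed before their results were seen, except that the mesothelial test was made to take the spread between markers into account after its value was seen.

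The 14 higher probe sets form the first pattern. Only 1 of the 35 splits of the 8 arrays, the real one, called as many, and the highest of the others called 1. That argues against chance as the source of the count but does not exclude it, since 1 of 35 is the smallest share the splits can give. Their median log2 fold change was 3.29 with all arrays and 3.07 without HHcy 5 and HHcy 6 (lower quartile 2.44). There 4 of the 14 still passed, with fewer arrays and a median SE of 0.47 in place of 0.42. It was 2.98 with median scaling, where 13 of the 14 passed. With quantile scaling it was 3.16, and 7 passed, without C6 and LOC403585. With the 3'/5' covariate 4 passed: C3, LOC751814, SAA1 and 1 of LOC403585. The 14 were called on all arrays together, each with every HHcy array above every control, so these medians could hardly fall far. They do not decide RNA quality, and show only that the higher signal is also present on HHcy 7 and HHcy 8 and under each scaling. A scaling factor applies to all probe sets of an array. Over all probe sets the median log2 fold change was 0.15, against 0.011 with quantile and -0.19 with median scaling. Each of the 14 changed by at least 2.47, so these values argue against scaling as the source of the 14. More macrophages of the kind in control hearts stay open: the 14 exceeded the macrophage markers by 2.02 in the median, but the threshold had let through no change under 2.47, above the 2.26 the test asked for, so it decides nothing. Mesothelial surface tissue stays open too. The 6 measured of 25 added markers had a median of 0.24 (camera p 0.883), under the bound of 0.25 set beforehand by less than their spread (upper quartile 0.36). EZR and DSP among them are already high in control hearts (6901 and 5058). KRT8 and KRT18, mesothelial markers also made by other epithelia, had folds of 5.23 and 4.53 (limma adjusted p 0.122 and 0.121). These folds are inexact: outside control 3 the KRT18 control signals were 16.9 to 20.3, under the pseudocount. Over the alternatives the log2 fold changes ran from 1.64 to 2.87 and from 1.34 to 2.71. RNA quality, more macrophages, mesothelial tissue and an effect of HHcy, the hypothesis the design names, thus cannot be told apart.

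HHcy 6 forms the second pattern. Its cardiomyocyte median was -4.77, while other genes of the same control level had a median of 0.21. The lowest of 10000 matched random lists drawn from these was -1.17. These other genes left out the myocyte, sarcomere, calcium, stress, fatty acid, TCA cycle, oxidative phosphorylation and creatine lists. Of those left out, oxidative phosphorylation and TCA cycle genes also fell on HHcy 6 (-2.15 and -1.72). The values thus argue only against a loss that lowers all genes of that level alike, and say nothing of a loss that took in the lists left out. Adipocyte, fibroblast and smooth muscle medians on that array were 2.11, 1.37 and 1.19, so a piece holding mostly fat or fibrous tissue may account for it. No biological explanation was tested.

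Macrophage markers form the third pattern. Their median exceeded the endothelial median by 1.35 log2 units in HHcy against control, and by 1.46 without PECAM1, whose probe set is named by annotation alone. For the first difference the exact two-sided permutation p was 0.0286, the smallest possible. Its adjusted p over 3 cell types was 0.0857, which did not pass. With 0.0286 the smallest possible, no contrast could pass after that adjustment unless another reached the same p. The adjusted test thus cannot decide, and a lower myocyte share raising all other types alike stays open. Against fibroblast and smooth muscle markers the differences were 0.53 and 0.54 (exact permutation p = 0.0571 and 0.0857), which did not pass. A lower myocyte share together with fewer endothelial transcripts stays open too. Without HHcy 5 and HHcy 6 the macrophage median was 0.96 (lower quartile 0.68, little above the 0.63 under which those arrays would account for the shift), against 1.26 with all arrays, which argues against those arrays as the whole cause. More macrophages, or a change in them, also stays open as a hypothesis.

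The list count differs in this respect: 3 of the 35 splits gave at least the real 15 lists and the highest other gave 16, so chance is not excluded. Both splits with 16 keep HHcy 5, HHcy 6 and HHcy 7 together.

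In groups of 4, chance puts 1 sample far from the rest in about 1 of 20 groups. Among 218 groups over the named genes this happened 22 times, 14 of them on HHcy 6, against 10.9 by chance. On HHcy 6 the signal was lowest for CCDC91 (578), MYL3 (27.4), TNNT2 (24.5), FHL2 (524), ACADM (12560), PDHA1 (3567) and ATP2A2 (4061). It was highest there for SLC2A3 (1973), CDO1 (13320), MAOB (1040), DGAT2 (17816), ACTA2 (28849), S100B (2281) and CAT (11889). Among 76 groups of list medians it happened 10 times, all on HHcy 6, against 3.8 by chance, and among 8 groups of array measures 2 times. The lists share members, so their groups are not independent. Elsewhere a sample stood apart for MVD (449 on HHcy 7), CD14 (479 on HHcy 8), PSMB1 (1890), KRT18 (79.0) and MAT2A (8633) on control 3, COL1A2 (452) and CD3D (79.0) on control 4, and SOD2 (2062) on control 2. List medians stood apart on HHcy 6 for cardiomyocyte (-4.77), sarcomere (-4.07), stress and fetal heart genes (-2.17), oxidative phosphorylation (-2.15), calcium handling (-2.07), the TCA cycle (-1.72), fatty acid oxidation (-0.86), hypoxia targets (-0.16), glycogen metabolism (0.43) and the circadian clock (0.89). Mean correlation with the other arrays was lowest within its group on control 2 (0.857) and on HHcy 6 (0.784).

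Control probe sets outside the comparison gave actin 3'/5' ratios above the highest control, 2.49, of 15.3 on HHcy 5, 599.6 on HHcy 6 and 2.67 on HHcy 7. GAPDH ratios above the highest control, 3.76, were 17.2, 10.5 and 5.14 on the same arrays.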

How the results depend on the processing

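No paired analysis was possible because the groups share no replicate number. The settings that leave out 2 arrays or use the 3'/5' covariate were chosen after the data were seen. The count of 14 was 8 with 1 probe set per gene, 7 with quantile scaling, 22 with median scaling (15 higher, 7 lower), 9 with the dimmest 60% left out (fewer were tested), 76 with array weights (61 higher, 15 lower), 5 without HHcy 5 and 6, 5 with the covariate and 3 to 31 without 1 array; 10 settings stayed within 1.5-fold, 2 of them with 1 array left out. The 15 lists were 0 with an estimated correlation, 2 with fry, 7 without HHcy 5 and 6, 8 without control 2 and HHcy 6, 3 with the covariate and 6 to 16 without 1 array. Where arrays are left out, fewer samples enter; the cause was not tested otherwise. The 14 probe sets were above 0 wherever tested.

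Signs turned for these log2 fold changes, none past the threshold under that alternative, and of these genes LOC403585 alone had passed in the comparison. On other probe sets of the gene: CALU 0.14, FAU 1.0, CCSER2 0.10, KCNA5 0.40, FN1 -0.17, MCM7 -1.66, VWF 1.29, PECAM1 -0.057, -0.16, -0.0057, -0.23 and -0.058, CD4 -1.29, NOS3 -0.14, SOD2 0.28, CAT -0.42 and -0.51, PDHA1 0.72, TXNIP -2.53, ATP2A2 0.029, 0.0062, 0.043 and 0.17, LOC403585 -0.39. With quantile scaling: AHCY -0.065, and the antioxidant (adjusted p 0.931) and immediate early lists (0.996583). With median scaling: PECAM1 -0.11, NOS3 -0.047, PDK4 -0.061, AHCY -0.30, and the ribosome list (0.840). With the dimmest 60% left out and with fry: the antioxidant list (0.849 and 0.721). With array weights: ACADM 0.075, UCP3 0.090, AHCY -0.042, and the adipocyte list (0.936). Without 1 array: UCHL1 -0.25 to 0.15, UCP3 -0.70 to 0.38, ACADM -0.28 to 0.037, AHCY -0.046 to 0.12, and the adjusted p of the antioxidant (0.433 to 0.990393), immediate early (0.344 to 0.990393) and adipocyte lists (0.239 to 0.962). Without HHcy 5 and 6: PECAM1 -0.0057, UCHL1 0.068, NOS3 -0.059, ACADM 0.011, AHCY -0.13, and the heat shock (0.988), antioxidant (0.490446) and immediate early lists (0.988). Without control 2 and HHcy 6: SOD1 -0.022, ACADM 0.12, UCP3 0.26, AHCY -0.083, ATP2A2 0.053, and the antioxidant (0.886), smooth muscle (0.759) and adipocyte lists (0.759). With the covariate: MYL3 0.59, TNNT2 0.92, FHL2 0.017, PECAM1 -0.072, ACTA2 -0.20, S100B -0.045, UCHL1 0.025, TNNC2 0.29, NOS3 -0.042, SOD1 -0.074, SOD2 0.13, ACADM 0.21, UCP3 0.42, GAPDH 0.58, AHCY -0.19, ATP2A2 0.34, and the lists of the TCA cycle (adjusted p 0.899), oxidative phosphorylation (0.480), heat shock (0.698731), sarcomere (0.698731), cardiomyocyte (0.381), ventricular (0.953), antioxidant (0.899), methionine (0.953), smooth muscle (0.899) and adipocyte genes (0.479999). Of the other comparisons of a named gene with its main value, 2232 kept sign and side of the threshold, 48 lost the call and 19 gained it. Signal over background limits dim genes, since 14.7% to 23.4% of an array's probe sets lay under the pseudocount.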

Other observations

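The settings that leave out 2 arrays were chosen after the data were seen. Ribosome, immediate early and cell cycle genes did not pass as lists in the comparison. Cytosolic ribosome genes had a median log2 fold change of 0.28 over 61 members (camera adjusted p 0.184), and passed as higher with the dimmest 60% left out (0.0464), with array weights (0.0319), without control 1 (0.0141), without HHcy 5 and HHcy 6 (0.0171) and without control 2 and HHcy 6 (0.0335). With median scaling the direction of that list turned (0.840). Over all alternatives its camera or fry adjusted p ran from 0.0141 to 0.981, and for camera with an estimated correlation it was 0.708. RPL11 had a fold of 2.07 (adjusted p 0.171). Immediate early genes had a median of 0.36 over 8 members (camera adjusted p 0.746), with FOS, a growth-response transcription factor, at a fold of 2.29 (adjusted p 0.144, and 0.0499 with array weights, range 0.0499 to 0.814; 1 member passed adjusted over the list alone). Cell cycle genes had a median of 0.52 over 7 members (camera adjusted p 0.148). Of the methionine list, BHMT, which remethylates homocysteine, had a fold of 2.93 and no overlap between groups (adjusted p 0.176), and CDO1, an enzyme of cysteine breakdown, had a fold of 4.21 (adjusted p 0.202) and a signal of 13320 on HHcy 6 against 853.7 to 1287.9 on the other HHcy arrays. Without HHcy 6 the log2 fold change of CDO1 was 1.19, against 2.07.

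Among cell types, endothelial markers had a median of -0.12 over 5 members (camera adjusted p 0.487) and smooth muscle markers 0.62 over 7 members (camera adjusted p 0.574). Fibroblast markers had 0.72 over 8 members (camera adjusted p 0.0977, range 0.00806 to 0.730) and adipocyte markers 0.39 over 5 members (camera adjusted p 0.574). The fibroblast list passed with the dimmest 60% left out (0.0315) and without HHcy 8 (0.00806), but its camera adjusted p was 0.546 with all arrays and an estimated correlation. PECAM1 among the endothelial markers had a control signal of 19334, and its probe set is named by the platform annotation alone. RBP4, a retinol carrier of fat and liver, had a log2 fold change of 3.40 (adjusted p 0.162), which was 2.48 without HHcy 6, where its signal was 21115, 2.53 without control 2 and 4.05 without HHcy 8. The T or B lymphocyte, Schwann cell and mesothelial lists had 3, 3 and 2 measured members and were not tested as lists, and the neutrophil, erythroid and sex-linked lists had 0.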
